A study of Saccharomyces cerevisiae with 31 samples.

How the data were processed

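RNA abundance was measured in 31 libraries of Saccharomyces cerevisiae, grouped by the source name in the labels into 3 elutriation experiments and 1 unelutriated time course of Cdc28-as cells with 1NM-PP1, and 2 control series of WT cells. Per the labels' protocols, cells grew in rich medium with ethanol, a known number of Candida albicans cells was added before extraction, total RNA was taken with hot acid phenol, and libraries were made with the NuGEN Ovation Universal RNA-Seq kit. Reads were aligned with Bowtie2 to build R64, per the submitters' processing notes. Counting, the use of strand, the depth normalization and any use of the added Candida reads are not given in the sources used here.

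The authors deposited 1 table of 6713 genes with a scaling score for each of the 6 series, a rank by the experiment 1 score and a median read count in experiment 1. The formula of the score is not given in the sources used here and was worked out from the values. If a gene is detected only in the first library, the least-squares slope of its abundance relative to that library on the labelled sizes is -0.0197 per fl in experiment 1 and -0.0218 per fl in experiment 3, and 104 and 111 genes hold exactly these scores (within 1e-07). In the WT controls the same slope on the labelled hours is -0.143 and -0.106 per hour, held by 96 and 44 genes, and a further 8 and 33 genes hold the slope for detection in the second library alone, taken relative to that library, so the formula above does not cover genes absent from the first library. In experiment 2 and the time course only 2 and 3 genes hold that slope, too few to check the formula, and it was assumed for these columns. Scores reached down to -0.264, -0.0468, -0.0218 and -0.397 per fl in experiments 1 to 3 and the time course, and up to 2.24, 0.732, 1.41 and 1.29 per fl. Because the level is relative to the first library, a gene that starts near 0 reads can score high by chance. On this formula an abundance proportional to cell size against a fixed amount of added RNA would score 0.0657, 0.0670, 0.0537 and 0.0464 per fl in experiments 1 to 3 and the time course. The median genes scored 0.00701, 0.0108, 0.00132 and -0.0201.

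The deposited median read count, a signal per gene that the authors did not scale, is not a whole number for 2779 genes although experiment 1 has 5 libraries. It is therefore not a plain median of 5 whole counts, and how it was made is not given in the sources used here. It summed to 282178, with 871 genes at 0 and 693 genes at 100 or more. Read counts per library were not used here, so no interval for counting error could be given. The deposited rank score differed from the rank of the experiment 1 score by at most 4 places. Of the 6713 identifiers, 6022 matched an R64 locus tag, which gave symbols and coordinates (1-based); the others keep the identifier of the authors' table. The names OCT1 and MAY24 had been turned into spreadsheet dates in the table and were restored from the identifier. A few lines of the table hold no values and were not analysed here.

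For each elutriation experiment the median gene's score was subtracted, over the 5771 genes scored in all 3. Each gene was tested with limma's one-sample moderated test across the 3 experiments, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 31 gene lists were compared with other genes by camera in limma with a preset inter-gene correlation of 0.01, for lists with at least 5 measured members, and again with an estimated correlation. G1/S activators and inhibitors were compared with a two-sided exact permutation test of the difference in medians. For single series, which allow no test across experiments, the percentile of each list's median among 10000 random lists of the same size, matched in 20 bins of read count, describes that series. Agreement between series was given as correlations across genes. Lists, main tests, groups and the rule for named genes were fixed before the data were examined. The rule names all G1/S activators, G1/S inhibitors and core histones, then the 10 highest and 10 lowest genes past the test or, as fewer passed, among genes on the same side of the median gene in all Cdc28-as series, then up to 4 members of each called list. Other genes named were chosen after their values were seen.

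The steps were tested on simulated scores for 5412 genes in the 3 elutriation experiments, drawn from the real sizes. The median read counts of experiment 1 served as the depth of all 3 experiments, and the spread of counts was assumed (negative binomial). The calls below therefore hold for that depth and spread only. Of 99 genes changed 10-fold limma called 2 and the product of ranks 98, and of 93 changed 3-fold they called 0 and 5. With no gene changed, the product of ranks called 3 genes and camera 0 lists. Genes were drawn independently, so the simulation could not test camera on lists whose genes move together. A ribosome biogenesis list raised 3-fold was called by camera with the preset correlation and not with the estimated one (adjusted p = 0.886).

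Alternatives left out each experiment in turn, added the time course, used the scores as deposited, named genes only, a read-count filter, scaled scores, a robust prior, rank-based normal scores, the score times the size span, random lists, means in place of medians, and subsets of the G1/S lists. Rank-based scores, the product of ranks, the size span, the read filters on lists, G1/S members and correlations, the correlation with the unelutriated control, and the G1/S difference in each experiment alone were chosen after the data were examined. A model with genotype and elutriation as terms, and elutriation scores less the control score, were not run because scores are per fl in one and per hour in the other. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.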

Results

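Transcript abundance was followed in budding yeast (Saccharomyces cerevisiae) as cells grew large without dividing. Cdc28-as cells carry an analog-sensitive form of Cdc28, the cyclin-dependent kinase that drives the cell cycle, and the bulky inhibitor 1NM-PP1 blocks this form. The 31 libraries fall into 6 series. In 3 elutriation experiments Cdc28-as cells were elutriated, a sorting by size in a centrifuge, and then given 1NM-PP1. Experiment 1 had 5 libraries from 15.23 to 50.77 fl (femtolitres) of cell size, experiment 2 had 3 from 14.92 to 41.8 fl, and experiment 3 had 3 from 18.61 to 66.46 fl. An unelutriated Cdc28-as time course had 8 libraries from 21.56 to 44.02 fl. Wild-type (WT) cells gave an elutriated control of 6 libraries from 2 to 7 h and an unelutriated control of 6 libraries from 0 to 6 h.

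The authors' deposited table holds 1 score per gene and series, with no values per library. In experiments 1 and 3 and the WT controls the scores behave, for genes detected in the first library, as the slope of abundance relative to that library, per fl of size in Cdc28-as cells and per hour in WT cells. In experiment 2 and the time course this could not be checked and was assumed. On this reading a score of 0 is a level that stayed the same along the series on the authors' scale. Whether that scale is a share of the library or an amount relative to the added Candida RNA is not given in the sources used here. A score of 0 can therefore mean a constant share and not a constant amount per cell. Changes given below as times the starting level are the score times the size span, on the same scale. They come from a fitted slope and are not measured differences between libraries. For the tests, the median gene's score was taken off in each series, and values after that step are called scores over the median gene. Read counts are given for experiment 1 alone, as the authors' median read count per gene, and how it was made is not given. It had a median of 19 over the 6713 genes, summed to 282178, and reached 10 reads in 66.6% of genes. The sum is not the depth of a library, and depth per library is unknown in every series. The labels do not say whether the 3 experiments came from separate cultures, so limma's p-values for single genes measure only the spread between these series. Camera with the preset correlation, the random lists and the permutation tests compare genes with genes. Their p-values rest on the spread across genes and do not measure how well the experiments agree.

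The first comparison asked which transcripts scale with size differently from the typical gene in the elutriated, arrested cells. Cells grew during the arrest, so a slope on size cannot be told apart from a slope on time in arrest or since elutriation. By limma's camera test with a preset correlation, genes that build ribosomes and genes of the G1/S wave of transcription scored above other genes, and general stress, daughter-specific, ethanol-use, vacuolar and autophagy genes scored below. None of these list calls held with a correlation estimated from the data, and random lists also ended those of the daughter-specific, ethanol-use, vacuolar and autophagy genes. The highest mean score belonged to GIC2, an effector of the polarity GTPase Cdc42, with authors' scores of 2.24, 0.0976 and 0.0446 per fl in experiments 1, 2 and 3. The G1 cyclin gene CLN2 scored 0.660, 0.172 and 0.104 per fl. HSP12, a small stress protein gene, scored -0.0371, -0.0231 and -0.0134 per fl.

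No single gene passed the test: limma called 0 of 5771 genes at an adjusted p of 0.05, with 519 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.460. In simulated data with no gene changed, a product of ranks called 3 genes, so some of its calls can be false. Over the 3 experiments this method, chosen after the data were examined, called 12 genes, all high. Their adjusted p values by the product of ranks lay between 0.0366 and 0.0478. Besides GIC2 and CLN2 the 12 genes were the cohesin gene MCD1, the tRNA dihydrouridine synthase gene DUS1, the ferric reductase gene FRE7, CSI2, the Hsp90 co-chaperone gene CPR7, the ribonucleotide reductase gene RNR1, PRY2, the G1 cyclin gene PCL1, the bud-site GTPase gene RSR1 and YGR151C. YGR151C overlaps RSR1, so their reads cannot be told apart without strand, and whether counting used strand is not given in the sources used here. Direction was shared more often than chance gives: 1287 genes (22.3%) lay above the median gene in all 3 experiments and 1301 (22.5%) below it, against 12.5% each by chance.

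Among the 1528 genes on the same side of the median gene in all 4 Cdc28-as series, the 10 with the highest mean were GIC2, MCD1, CSM3, CLB2, YGR151C, CLN2, CSI2, CTM1, SME1 and ARG1. The MCD1 gene (chromosome IV, 444683 to 446383, R64) scored 1.41, 0.146 and 0.0281 per fl. CLB2, a mitotic cyclin gene with a median of 5 reads in experiment 1, scored 1.03, 0.196 and 0.0139 per fl. GIC2 (chromosome IV, 1079048 to 1080199) lay 0.786 per fl over the median gene with a limma SE of 0.532 and an adjusted p of 0.509, and 0.0647 per fl over it without experiment 1. The means of the other highest genes were also lower without experiment 1, except that of YGR151C, which was 0.316 with and 0.434 without it. The 10 lowest were YLR171W, RRT5, AQY1, YIL100C-A, EDC1, YKL076C, LSM8, YER053C-A, YPR050C and BNA2. Their authors' scores lay between -0.0781 and 0.000137 per fl in the 3 experiments, and their median read counts between 0 and 19.

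Of 31 gene lists fixed before the data were examined, limma's camera test with a preset correlation called 12, with 7 above and 5 below other genes. With a correlation estimated from the 3 experiments it called 0, and the adjusted p values of those 12 lists then lay between 0.624 and 0.762. Against 10000 random lists of the same size, 7 of the 12 calls held, and the G1/S activator, daughter-specific, ethanol-use, vacuolar and autophagy calls were lost. The random lists draw genes independently, so they leave out correlation between the genes of a list. The estimated correlation of the 12 lists ran from 0.0128 (ethanol use) to 0.872 (cytosolic ribosomal proteins). In simulated data camera with an estimated correlation missed a list raised 3-fold, at an adjusted p of 0.886. Simulated genes were drawn independently, so this could not show whether the preset value is safe for the real lists. Adjusted over the list alone, limma called 1 gene, RPC82 of RNA polymerase III (0.0596, 0.0757 and 0.0458 per fl), and 0 in each other list.

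The 37 tested genes of the G1/S regulon, the targets of the transcription factors SBF and MBF, scored 0.0991, 0.0342 and 0.0224 per fl over the median gene in experiments 1, 2 and 3, as list medians (camera adjusted p = 4.03e-07, and adjusted p = 0.624 with an estimated correlation). Of these, 19 lay above the median gene in all 3 experiments and 0 below. RNR1 scored 0.441, 0.191 and 0.0746 per fl, and CSI2 0.657, 0.205 and 0.0503 per fl. At the other end of G1, the 19 daughter-specific and SIC1-cluster genes, which act from mitotic exit into early G1, scored -0.0230, -0.00780 and -0.0105 per fl over the median gene (camera adjusted p = 0.00277, adjusted p = 0.624 with an estimated correlation, and adjusted p = 0.0575 against random lists). Of these, 9 lay below the median gene throughout and 1 above. The chitinase gene CTS1 scored -0.0205, -0.0257 and -0.0174 per fl, and DSE3 scored -0.0175, -0.0123 and -0.0132 per fl.

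Ribosome biogenesis genes, which process and assemble pre-ribosomes, scored 0.0443, 0.0573 and 0.00875 per fl over the median gene as medians of 48 genes (camera adjusted p = 7.14e-10, and adjusted p = 0.624 with an estimated correlation). Of the 48, 31 lay above the median gene in all 3 experiments and 0 below. UTP6 scored 0.423, 0.215 and 0.0214 per fl and CIC1 0.307, 0.139 and 0.0412 per fl. The 18 tested subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, scored 0.0797, 0.0640 and 0.00876 per fl over the median gene (camera adjusted p = 1.42e-05, and adjusted p = 0.624 with an estimated correlation). In this list 13 lay above the median gene throughout, among them RPC31 (0.263, 0.103 and 0.0540 per fl) and RPA12 (0.125, 0.252 and 0.0302 per fl). RNA polymerase II subunits were not called (median of means 0.00675 per fl over the median gene, camera adjusted p = 0.274).

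Cytosolic ribosomal protein genes scored 0.0722, 0.00645 and 0.00219 per fl over the median gene as medians of 138 genes (camera adjusted p = 7.14e-10, and adjusted p = 0.762 with an estimated correlation). Of these, 75 lay above the median gene in all 3 experiments and 0 below. RPS9A scored 0.409, 0.10 and 0.0189 per fl, and RPL4A 0.327, 0.0262 and 0.00334 per fl. The list rests on experiment 1: without it camera no longer called the list. It also holds RPP1, an RNase P subunit gene that the pattern of names took in (0.125, 0.199 and 0.00839 per fl), and many members have a near-identical copy; how reads that match both copies were counted is not given in the sources used here. Translation factors and tRNA synthetases scored 0.0405, 0.0174 and 0.00337 per fl over the median gene, with 23 of 40 above it throughout (camera adjusted p = 7.30e-07, and adjusted p = 0.664 with an estimated correlation). NIP1, a subunit of initiation factor eIF3, scored 0.135, 0.104 and 0.00196 per fl, and the asparaginyl-tRNA synthetase gene DED81 0.0963, 0.0878 and 0.0160 per fl. Mitochondrial ribosomal proteins, encoded in the nucleus, scored 0.0297, 0.00469 and 0.00805 per fl over the median gene, with 37 of 70 above it throughout (camera adjusted p = 1.12e-06, and adjusted p = 0.658 with an estimated correlation). MRPL9 scored 0.0894, 0.0682 and 0.0234 per fl.

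General stress and heat shock genes scored -0.0178, -0.0248 and -0.0117 per fl over the median gene (camera adjusted p = 7.14e-10, and adjusted p = 0.624 with an estimated correlation). Of the 33 genes, 26 lay below the median gene in all 3 experiments and 1 above. The catalase gene CTT1 scored -0.0209, -0.0220 and -0.0174 per fl, the glycogen branching enzyme gene GLC3 -0.0124, -0.0207 and -0.0171 per fl, and the chaperone gene HSP42 -0.0104, -0.0234 and -0.0163 per fl. Genes for ethanol use, the glyoxylate cycle and gluconeogenesis, pathways that serve growth on the ethanol medium used here, scored -0.0126, -0.0125 and -0.00703 per fl over the median gene (camera adjusted p = 0.00542, adjusted p = 0.624 with an estimated correlation, and adjusted p = 0.122 against random lists). In that list 7 of 14 lay below the median gene throughout, among them the acetyl-CoA synthetase gene ACS1 (-0.0171, -0.00808 and -0.0121 per fl) and FBP1 (-0.0140, -0.0123 and -0.00994 per fl), which encodes fructose-1,6-bisphosphatase. The vacuolar ATPase and proteases scored -0.00714, -0.0123 and -0.00428 per fl over the median gene, with 9 of 21 below it throughout (camera adjusted p = 0.0162, and adjusted p = 0.624 with an estimated correlation). The vacuolar protease gene PRB1 scored -0.0184, -0.0178 and -0.00779 per fl. Autophagy genes scored -0.0123, -0.00290 and -0.00706 per fl over the median gene, with 10 of 22 below it throughout (camera adjusted p = 0.0309, and adjusted p = 0.624 with an estimated correlation). ATG4 scored -0.0155, -0.0134 and -0.00938 per fl. Leaving out experiment 2 ended the vacuolar call, and leaving out experiment 1 or experiment 3 ended the autophagy call. Random lists ended both, at adjusted p values of 0.0575 and 0.121.

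**Figure D1:**
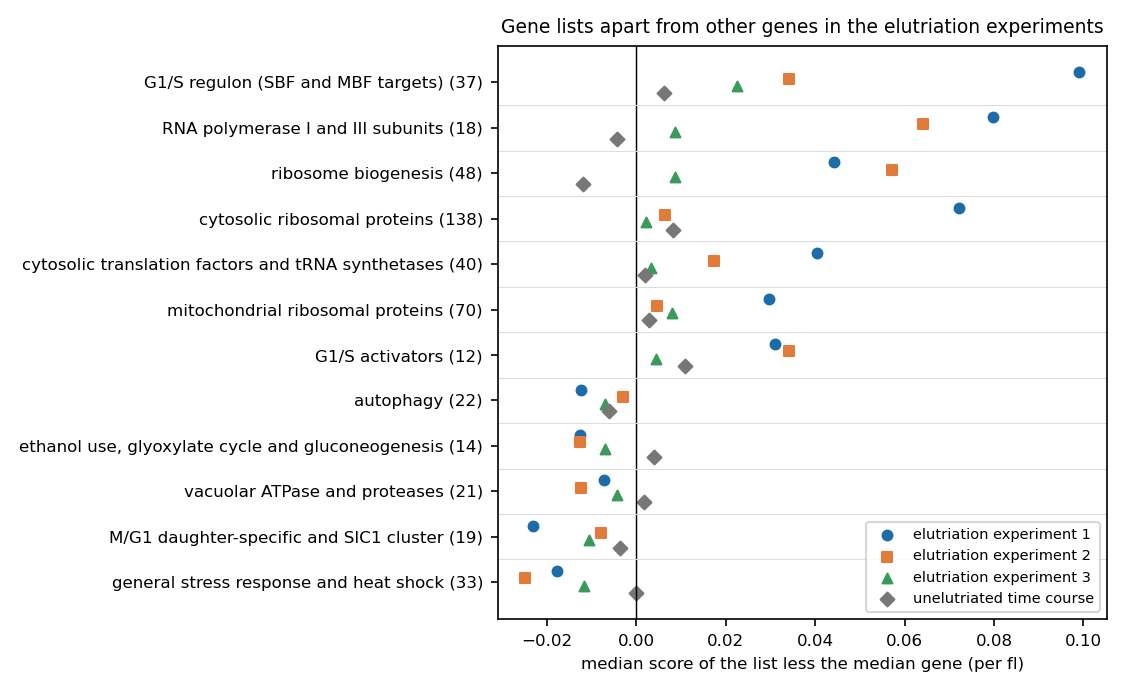
Median score of each gene list less the score of the median gene, per fl, for the 12 lists that camera called, with the number of tested genes in parentheses. Each marker is 1 series, circles, squares and triangles for elutriation experiments 1, 2 and 3 and diamonds for the unelutriated time course, with no error bars because each series has 1 score per gene; ribosome biogenesis lies at 0.0443, 0.0573 and 0.00875 in the elutriation experiments and at -0.0120 in the time course.

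Core histone genes, which package the genome, were not called (median of means -0.00197 per fl over the median gene, camera adjusted p = 0.987). HTA2, HTB2 and HHF2 lay above the median gene in all 3 experiments, at 0.0675, 0.0356 and 0.0186 per fl for HTA2, 0.0279, 0.0751 and 0.0106 for HTB2, and 0.0245, 0.0361 and 0.0178 for HHF2. HHT1 scored -0.00773, -0.00719 and -0.00568 per fl and HHF1 -0.00717, -0.0168 and -0.00119 per fl, both below the median gene in all 3. HTA1 scored -0.0147, 0.0126 and -0.00105 per fl, HTB1 0.00186, 0.00721 and 0.00792, and HHT2 0.00613, -0.00033 and 0.00565. Each of these genes has a near-identical copy, and how reads that match both copies were counted is not given in the sources used here.

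The lists that follow were not called, and the values are medians of means in per fl over the median gene. Among cell-cycle lists, the CLB2 cluster of the G2/M regulon had 0.0166 by camera in limma (adjusted p = 0.171), the MCM helicase and origin licensing genes 0.00556 (adjusted p = 0.409), spindle pole body and tubulin genes 0.0135 (adjusted p = 0.171) and kinetochore genes -0.000545 (adjusted p = 0.598). Energy lists had 0.00410 for oxidative phosphorylation (adjusted p = 0.297), 0.00496 for the TCA cycle (adjusted p = 0.708) and -0.00310 for glycolysis (adjusted p = 0.165) by camera in limma. Surface and secretion lists had 0.00600 for the cell wall (adjusted p = 0.673), 0.00381 for the secretory pathway and ER folding (adjusted p = 0.165) and 0.00227 for ergosterol synthesis (adjusted p = 0.738). The proteasome had -0.00180 (adjusted p = 0.395), the nuclear pore 0.00525 (adjusted p = 0.165), mating and pheromone response 0.0172 (adjusted p = 0.165), meiosis and sporulation 0.00873 (adjusted p = 0.964) and the phosphate and starvation response -0.00504 (adjusted p = 0.0999). Genes of the mitochondrial genome had -3.86e-06 (adjusted p = 0.954). The median and the mean of means differed in sign for the kinetochore (mean 0.00762), core histone (mean 0.00551), mitochondrial genome (mean 0.00155) and G1/S inhibitor lists (mean 0.00406).

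The second comparison set activators of the G1/S transition against its inhibitors, a question the series title raises in naming size control. The CDK gene CDC28 itself (chromosome II, 560078 to 560974), whose analog-sensitive allele these cells carry, scored 0.286, 0.127 and 0.0875 per fl. The upstream G1 cyclin gene CLN3 (chromosome I, 65778 to 67520) scored 0.0515, 0.0581 and 0.000662 per fl, and the cyclin gene CLN1 0.0848, 0.0915 and 0.0115 per fl. WHI5 (chromosome XV, 479533 to 480420), which encodes the inhibitor of SBF, scored -0.0264, -0.0117 and -0.0199 per fl, with a median of 1 read in experiment 1. Multiplied by the size span these scores give 1.83, 1.56 and 0.0317 times the starting level for CLN3 and -0.940, -0.315 and -0.952 times for WHI5. Such products are not shares lost or gained, since they reached -2.78 for YLR171W in experiment 1. In experiment 3 WHI5 lay near the lowest score, -0.0218 per fl, which 111 genes held.

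The other activators were mixed. The S-phase cyclin gene CLB5 scored 0.0872, 0.0163 and 0.0537 per fl and the CDK subunit gene CKS1 0.0403, 0.00912 and 0.0143 per fl. SWI4, the DNA-binding subunit of SBF, scored 0.0029, 0.0205 and 0.0337 per fl, while SWI6, shared by SBF and MBF, scored 0.00956, 0.0323 and -0.0104 per fl. MBP1 scored -0.0071, 0.0594 and -0.00788, BCK2 0.0367, 0.0172 and -0.00687, MSA1 0.00719, 0.00192 and -0.0101, and MSA2 0.000635, 0.0710 and -0.0101 per fl. CLB6 had no score in experiment 1 and scored -7.2e-05 and 0.0418 per fl in the others. Of the 12 tested activators, 4 lay above the median gene in all 3 experiments and 1 below, with list medians of 0.0311, 0.0342 and 0.00430 per fl over the median gene (camera adjusted p = 0.0309, and adjusted p = 0.624 with an estimated correlation). Camera no longer called this list without experiment 2, and random lists gave it an adjusted p of 0.265. CLN1, CLN2 and CLB5 are also SBF or MBF targets and stand in both lists.

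Among the 9 inhibitors, 4 lay below the median gene in all 3 experiments and 1 above (camera adjusted p = 0.203 in limma). XBP1, a stress-induced repressor, scored -0.0218, -0.00941 and -0.00444 per fl. The RNA-binding protein gene WHI3 scored 0.00442, -0.00261 and -0.0155 per fl and its relative WHI4 -0.00217, 0.00651 and -0.0101 per fl. SIC1, which encodes the inhibitor of S-phase CDK, scored -0.0182, 0.0272 and -0.00398, and the WHI5 relative SRL3 -0.000547, 0.0255 and -0.00763 per fl. FAR1, the pheromone-response CDK inhibitor gene, lay above the median gene in all 3 at 0.165, 0.0197 and 0.0133 per fl. STB1 scored 0.147, -0.00244 and 0.00357, and NRM1 -0.00782, 0.0256 and 0.0171 per fl.

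The median of mean scores was 0.0142 per fl over the median gene for the 12 activators and -0.00504 for the 9 inhibitors, a difference of 0.0192 that missed the threshold (exact permutation test over genes, two-sided, p = 0.0849). Genes are not independent replicates of each other, so this test describes these lists only. In each experiment alone, a split chosen after the data were examined, the difference was positive, at 0.0406 (exact permutation p = 0.126), 0.0387 (exact permutation p = 0.0038) and 0.0105 (exact permutation p = 0.350). Left out in turn, experiments 1, 2 and 3 gave 0.0277 (exact permutation p = 0.00591), 0.0277 (exact permutation p = 0.0968) and 0.0269 (exact permutation p = 0.116). It was 0.0223 without the SBF, MBF and M/G1 targets (exact permutation p = 0.02), 0.0503 as a difference in means (exact permutation p = 0.0645) and 0.0171 for members with at least 10 reads (exact permutation p = 0.136). The targets left out were CLN1, CLN2, CLB5, NRM1, SIC1 and FAR1, the inhibitor with the highest mean score. The 9 activators and 6 inhibitors that remained had medians of 0.0123 and -0.00994 per fl.

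**Figure D2:**
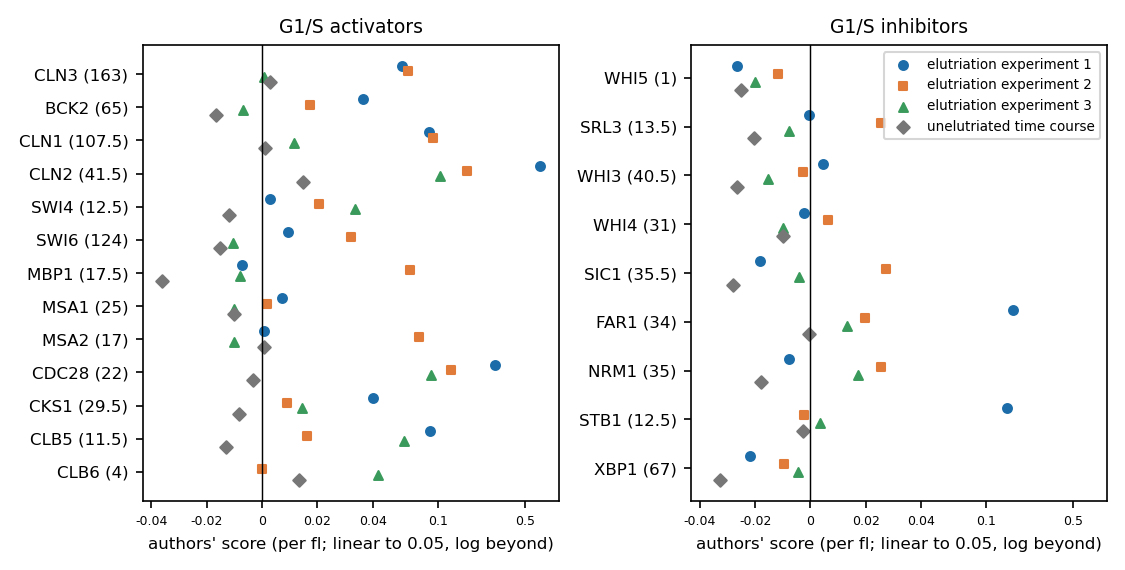
The authors' scores, per fl, of 13 G1/S activators and 9 G1/S inhibitors in the 3 elutriation experiments and the unelutriated time course, with each gene's median read count in experiment 1 in parentheses; the axis is linear to 0.05 and logarithmic beyond, and each marker is a single score without an error bar. CLN2 reaches 0.660 in experiment 1, and WHI5, with a median of 1 read, lies below 0 in all 4 series, between -0.0264 and -0.0117. In the time course 95.3% of all scored genes lie below 0 and the median gene lies at -0.0201, so a score below 0 there is not particular to WHI5.

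The third comparison asked whether arrested cells that grew without elutriation gave the same ordering of genes. The 5 highest scores of the time course all belonged to the mitochondrial genome, to COX1 and reading frames that overlap it. COX1, which encodes subunit 1 of cytochrome c oxidase (mitochondrial genome, 13818 to 26701), scored 1.23 per fl, a change of 27.7 times its starting level over the size span if the score is the assumed slope. COX2 scored 0.515 and COB, the cytochrome b gene, 0.546 per fl. In the elutriation experiments COX1 scored 0.0062, 0.0207 and 0.0188 per fl. The median of the 10 mitochondrial genes scored in all of these series, most of which overlap COX1 or COB, was 0.824 per fl over the median gene in the time course.

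Nuclear genes scored mostly below 0 in the time course, with a median of -0.0202 per fl, quartiles of -0.0267 and -0.0138, and 95.5% of genes below 0. G1/S regulon genes lay at 0.0063 per fl over the median gene, at percentile 99.99 of 10000 random lists matched on read count, and cytosolic ribosomal proteins at 0.00825 per fl. G1/S activators lay at 0.0109 per fl over the median gene and inhibitors at -0.000288 per fl, a difference of 0.0112 (exact permutation test over genes, p = 0.0726). Mitochondrial ribosomal proteins lay at 0.00273 and autophagy genes at -0.00611 per fl, on the same side as in the elutriation experiments. Ribosome biogenesis genes lay at -0.0120 per fl, at percentile 0, and RNA polymerase I and III subunits at -0.00441 per fl, both opposite in sign to the elutriation experiments. CLN2 scored 0.0147 per fl and WHI5 -0.0252 per fl.

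Across 5758 genes, which are not independent replicates, mean elutriation scores and time course scores had a Spearman correlation of 0.133 and a Pearson correlation of 0.00916, with 56.1% of genes on the same side of the median gene in both. Experiment 1 gave 0.210, experiment 2 gave 0.0143 and experiment 3 gave 0.0821 on their own. Between elutriation experiments the Spearman correlation was 0.350 for 1 and 2, 0.346 for 1 and 3, and 0.327 for 2 and 3. It depended on read count: in the 20% of genes with the fewest reads it was 0.161, 0.221 and 0.108, and in the 20% with the most reads 0.499, 0.451 and 0.544. The time course is a single series, so its gene and list values have no replicate check.

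**Figure D3:**
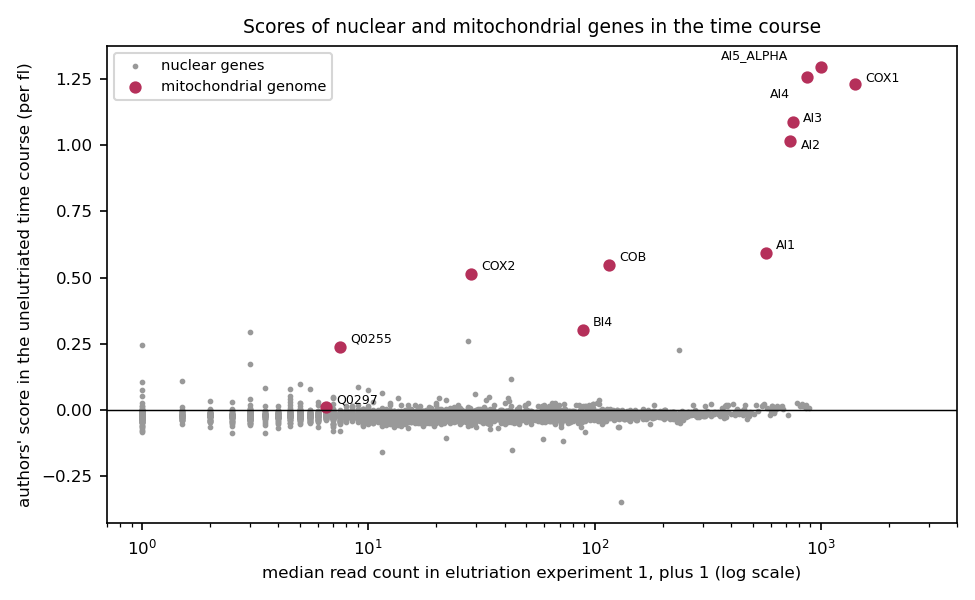
The authors' score in the unelutriated time course, per fl, against the median read count in elutriation experiment 1 plus 1 on a logarithmic axis, for nuclear genes with scores in all 3 elutriation experiments (grey) and the 11 mitochondrial genes scored in the time course (red). Nuclear genes centre on -0.0202, and COX1 lies at 1.23.

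**Figure D4:**
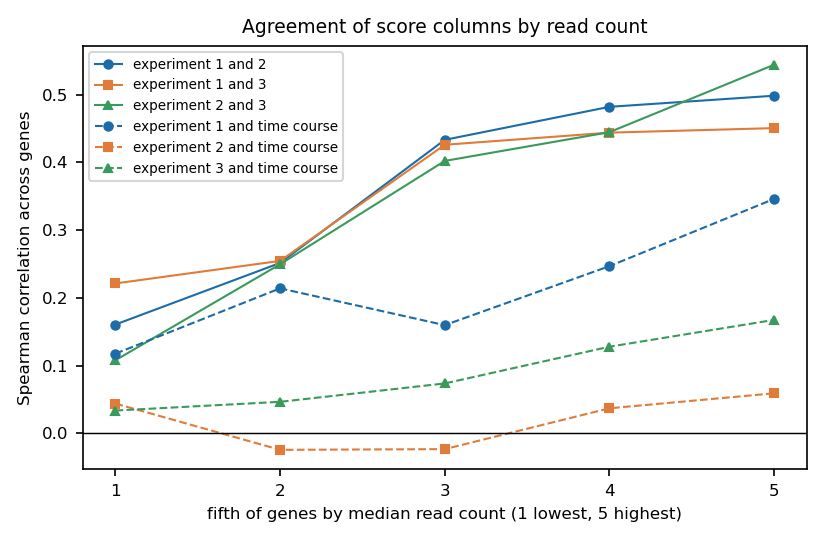
Spearman correlation across genes between pairs of score columns, for genes split by median read count in experiment 1 into equal groups from 1 (lowest) to 5 (highest). Solid lines join pairs of elutriation experiments and dashed lines pairs with the time course; experiments 2 and 3 go from 0.108 to 0.544.

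The fourth comparison set scaling in arrested cells against drift with time in WT cells, whose Cdc28 the inhibitor does not block. In the elutriated WT control, glycolysis genes scored 19.9 per hour over the median gene, oxidative phosphorylation genes 13.3, cytosolic ribosomal proteins 10.2 and translation factors 10.1. Stress genes scored 1.10 per hour over the median gene, at percentile 92.3 of matched random lists, and ribosome biogenesis genes 0.103 per hour, at percentile 46.3. Over all scored genes the elutriated control had a median of 0.136 and an SD of 11.0 per hour, against -0.0390 and 0.163 in the unelutriated control. A level near 0 in the first library would raise scores, so the high values of the elutriated control cannot be read as drift alone. Counts in that library were not used here. In the unelutriated WT control, TCA cycle genes scored 0.218 per hour over the median gene, cytosolic ribosomal proteins 0.0685 and mitochondrial ribosomal proteins -0.0442. G1/S regulon genes scored -0.120 and 0.0153 per hour over the median gene in the elutriated and unelutriated controls. WHI5 scored 0.0425 and 0.229 per hour, and CLN3 2.04 and 0.116 per hour.

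Mean elutriation scores had a Spearman correlation across genes of 0.0342 with the elutriated WT control over 5495 genes and of -0.0367 with the unelutriated WT control over 5473 genes. Among the 20% of genes with the most reads these were 0.178 and 0.0546, and experiment 1 alone gave 0.277 with the elutriated control. The unelutriated time course had a correlation of 0.193 with the unelutriated WT control over 5469 genes, and of 0.325 in the 20% with the most reads. Its like values were 0.133 and 0.243 with mean elutriation scores, and 0.210 and 0.346 with experiment 1 alone. Elutriated control scores themselves followed read count (Spearman correlation 0.348 across genes, against 0.164 in experiment 1) and reached 378 per hour for the actin gene ACT1. WT scores are per hour and arrested-cell scores per fl, so their sizes were not compared. The 28 mitochondrial genes in the table are blank in both WT columns.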

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

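All tests in this part were chosen after the values they concern had been seen. Several lists changed side of the median gene between the 3 elutriation experiments and the unelutriated time course, and these differences were not tested. In the time course the median lay at -0.0120 per fl for ribosome biogenesis and -0.00441 for RNA polymerase I and III subunits, both above the median gene in each elutriation experiment. It lay at 0.00387 for ethanol use, glyoxylate cycle and gluconeogenesis, 0.00175 for the vacuolar ATPase and proteases and 6.71e-06, in effect at the median gene, for general stress and heat shock, all below the median gene in each elutriation experiment.

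High scores of the ribosome synthesis lists and low stress scores in elutriated cells were set against recovery from elutriation and against growth during arrest, list by list, as percentiles of matched random lists. Growth during arrest, elutriated or not, is argued against as the only cause for ribosome biogenesis, at percentile 0 in the time course. There cytosolic ribosomal proteins lay at percentile 100 and mitochondrial ribosomal proteins at 98.9, the same way as in the elutriation experiments, while RNA polymerase I and III subunits (5.6), translation factors (51.8) and stress genes (27.9) lay within the middle 95% and decided nothing. Drift with time in unelutriated cultures stays open beside growth for some lists. In the unelutriated WT control ribosome biogenesis lay at percentile 5.22 (within the middle 95%), RNA polymerase I and III subunits at 2.13 and cytosolic ribosomal proteins at 99.7. These directions are the same as in the time course. Mitochondrial ribosomal proteins lay at 0.04 in that control, against 98.9 in the time course, which argues against such drift for that list. Stress genes (87.2) and translation factors (66.3) lay within the middle 95% in that control. Recovery stays open. In the elutriated WT control cytosolic ribosomal proteins and translation factors both lay at percentile 100, as recovery would give. Lists unrelated to ribosomes lay as high, among them glycolysis (100), oxidative phosphorylation (99.965) and the cell wall (99.97), so this is not particular to ribosome synthesis. Ribosome biogenesis (46.3), RNA polymerase I and III subunits (30.8), mitochondrial ribosomal proteins (47.1) and stress genes (92.3) lay within the middle 95%. That control starts at 2 h, its scores followed read count and spread widely (SD 11.0 per hour), and its cells were not arrested. This limits what it can show or exclude. The state of the cells at the start of each series was not tested.

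In the time course most scored genes of the mitochondrial genome lay far above nuclear genes, of which 95.5% scored below 0, a share that a few abundant transcripts taking a growing part of the reads could give. A rise with size in every arrested series is argued against, because the median of these genes over the median gene was -0.0228 per fl in experiment 1 (percentile 0 of matched random lists). It was 0.0101 in experiment 2 (percentile 94.5) and 0.0209 in experiment 3 (percentile 100), so a smaller rise there is not excluded; the highest of the 3 was 0.025 of the time course value. Reads shared by the overlapping frames of COX1 and COB stay open as a part of the pattern, because only 2 separate loci outside them were scored. COX2 (0.515 per fl, with Q0255 overlapping it at 0.239) lay above the 99th percentile of nuclear genes (0.0246), and Q0297 (0.0103) lay below it. Whether mitochondrial transcripts rose in these cells or entered the libraries more readily stays open, with no WT values for these genes. No biological explanation was tested.

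In experiment 1, 62 genes scored above 0.3 per fl, against 15 and 6 in experiments 2 and 3. Chance from few reads in its first library alone is argued against: of its 100 highest genes, 84 and 77 lay above the median gene in experiments 2 and 3. Their size was not kept. From scores over the median gene, the median change over the size span was 11.3 times the starting level in experiment 1. It was 1.28 in experiment 2 and 0.586 in experiment 3, ratios of 0.113 and 0.052. Part of that drop follows from choosing genes by experiment 1, and the spread of all genes times the span was also larger there (2.84, against 1.14 and 1.55). Whether few reads gave the size of these scores stays open: the 100 genes had a median of 18 reads, against 24.5 for all genes tested, and 28 of them lay in the lowest of 5 equal groups by read count, where chance gives 12 to 28 (95% binomial range). Counts in the first library were not used here. No biological explanation was tested.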

How the results depend on the processing

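Rank-based scores, the product of ranks, the size span, the read filters on lists, G1/S members and correlations, the correlation with the unelutriated control, and single experiments for the G1/S difference were chosen after the data were examined. The limma count of 0 genes held under 11 alternatives, with 154 to 1257 genes at an unadjusted p under 0.05; the product of ranks gave 12, and asking only for 1 direction and a mean over 0.5 gave 2, GIC2 and MCD1, because neither asks for a small spread between experiments. Of 12 called lists, an estimated correlation kept 0 and random lists 7, which lost G1/S activators (adjusted p = 0.265), ethanol use (adjusted p = 0.122), autophagy (adjusted p = 0.121), and the vacuolar and M/G1 lists (both adjusted p = 0.0575). Leaving out an experiment gave 11 to 13 called lists, of which 10 or 11 were among the 12. Without experiment 1 the mitochondrial genome and glycolysis lists were gained, and without experiment 2 oxidative phosphorylation, mating and phosphate lists. The size span ended the call of the G1/S activators and rank-based scores that of autophagy. The activator-inhibitor difference of 0.0192 lay between 0.0269 and 0.0277 with an experiment left out and passed the threshold without experiment 1 (exact permutation p = 0.00591), in experiment 2 alone (0.0387, exact permutation p = 0.0038) and without SBF, MBF and M/G1 targets (0.0223, exact permutation p = 0.02). It missed the threshold without experiment 2 or 3, as means and with a read filter. It was reversed in the unelutriated WT control (-0.113 per hour, exact permutation p = 0.357) and 0.839 per hour in the elutriated one (exact permutation p = 0.503); the cause was not tested. The time course correlation of 0.133 was 0.0143 with experiment 2 alone and 0.243 in the 20% of genes with the most reads. The elutriated WT correlation of 0.0342 was 0.178 in those genes and -0.0367 with the unelutriated control; the cause was not tested. For named genes 433 alternative values stayed within 1 SD and 12 moved further. Leaving out 1 of 3 scores cannot move their mean by 1 SD of those scores, so this count does not measure stability. For lists 219 alternatives kept their side of the threshold, 24 lost it and 5 gained it. No paired analysis was possible because the numbers in the labels mark size or time points and each series gives 1 score per gene. The genotype model and the scores less the control score were not run, since their units differ. Agreement between elutriation experiments was lower at low depth, with Spearman correlations of 0.108 to 0.221 in the 20% of genes with the fewest reads and 0.451 to 0.544 in the 20% with the most. In simulated data limma called 2 of 99 10-fold changes and the product of ranks 98, at 1 depth, so how depth affects the limma count was not tested.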

Other observations

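Beyond the mitochondrial genome, TAR1 (YLR154W-C) and RRT15 (YLR162W-A) were among the highest nuclear genes of the time course. Reading frames with neighbouring identifiers were high as well: YLR154W-B at 0.296, YLR154C-G at 0.228, YLR154W-A at 0.172 and YLR162W at 0.171 per fl. Whether these frames share reads was not tested, so they cannot be taken as separate observations. RRT15 had a median of 0 reads in elutriation experiment 1 and TAR1 26.5. In the time course TAR1 scored 0.259 per fl and RRT15 0.245 per fl. In elutriation experiments 1, 2 and 3 TAR1 scored -0.0403, -0.00452 and -0.00238 and RRT15 -0.0489, -0.0182 and -0.00639 per fl. The mating-factor gene MF(ALPHA)2 scored 0.599 per fl in the time course, with a median of 0 reads in elutriation experiment 1. At the low end of the time course ANB1, the hypoxic form of the translation factor eIF5A, scored -0.397 per fl (median of 2.5 reads). The GABA permease gene UGA4 scored -0.157 per fl (median of 10.5 reads). These genes were chosen after their values were seen, and the time course has no replicate.

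In single elutriation experiments a few genes stood out alone. OSI1 scored 1.41 per fl in experiment 3, with a median of 2 reads in experiment 1, and -0.0206 and 0.00483 in experiments 1 and 2. RPC11, a subunit gene of RNA polymerase III, scored 0.732 per fl in experiment 2, the highest score there, and 0.0598 and 0.0112 in the others. In the unelutriated WT control the highest score was 2.80 per hour, for the pseudouridine synthase gene PUS7.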
